A study of Homo sapiens with 4 samples.

How the data were processed

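Per the labels, HepG2 cells, a human liver cancer line, were infected with lentiviruses that expressed short hairpin RNAs, and all cells then received 10 µM sorafenib, a multikinase inhibitor, for 48 hours. The series has 4 libraries, with 1 from Control hairpin cells, 1 from each of 2 hairpins against ATF7IP and 1 from a hairpin against SETDB1. Cells were grown in DMEM with 10% fetal bovine serum, RNA was extracted with Trizol, and polyA RNA was sequenced with DNBSEQ-G400 protocols, per the labels' protocols. Every library was treated with sorafenib, so no comparison with untreated cells was possible.

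The deposited table held estimated counts (expected counts) per gene symbol for the 4 libraries, without normalization between libraries. The submitters' processing notes name HISAT2 2.2.1, StringTie 2.2.1, DESeq2 1.34.0 and the assembly hg38, without giving the role or order of each. The annotation and the counting procedure were not given in the sources used here. The deposited values were whole numbers, so no rounding was needed. Low values piled up at 4 and 8, with 489 Control genes at 4 against 288 at 3 and 265 at 5, and 276 at 8 against 203 at 7 and 174 at 9. The step at 12 was small, with 138 genes against 129 at 11, and 309, 257 and 288 genes were at 1, 2 and 3. About 4 counts per sequenced fragment were assumed from these steps, which no source states, and the floor, the fragment numbers and the exact intervals rest on that assumption. The table had 28278 genes, of which 7608 were at 0 in all 4 libraries, and 0 columns belonged to no sample. Gene positions, gene types and overlapping genes were taken from the RefSeq annotation of the same assembly for the 27656 symbols that matched it, and 2 list members were found under an older symbol.

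The library totals were 70236882 counts for Control, 71225287 and 73791097 for ATF7IP hairpins 1 and 2, and 72599883 for SETDB1 knockdown. A gene was treated as not detectable in a library at or under a floor of 3 fragments, taken as 12 counts, which was 0.171, 0.168, 0.163 and 0.165 CPM in the same order. All intervals and floors cover counting error only, since PCR copies are not independent molecules. CPM of named genes and of list members used trimmed mean of M values (TMM) library sizes, with factors of 0.990, 0.991, 1.04 and 0.980. The levels of cell type genes and the floors used the library total without TMM.

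Genes were tested with the edgeR (4.0.16) quasi-likelihood test in R 4.3.3. The default filterByExpr filter with a minimum count of 10 left 16900 genes. Dispersions came from robust estimateDisp and robust glmQLFit in its legacy form, and p-values were adjusted by Benjamini-Hochberg over the genes tested. All 4 libraries were fitted in 3 groups, and the comparisons were ATF7IP knockdown against Control, SETDB1 knockdown against Control and SETDB1 against ATF7IP knockdown. A gene was called at an adjusted p under 0.05. The p-values rest on 1 residual degree of freedom, the spread between the 2 ATF7IP hairpin libraries, moderated across genes with a median of 8.09 prior degrees of freedom. These 2 libraries came from cells with different hairpins, so their spread mixes differences between hairpins, cell populations and libraries. With 1 library per hairpin these parts cannot be told apart. Control and SETDB1 knockdown were assumed to vary like the ATF7IP libraries. The common dispersion was 0.0560, a biological coefficient of variation of 0.237. Log2 fold changes are given with the standard error of the fit.

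A size rule without a test counted genes at least 2-fold apart in log2 CPM with a prior count of 2, in the same direction in each library compared, with a mean of at least 1 CPM. For a gene at 0 in every library of a group, the fold change is a lower bound against the floor in each of those libraries, and for a gene with 1 to 3 fragments in a group it is a ratio with its 95% exact interval. Read-through loci, annotated as transcripts that run across neighbouring genes, numbered 175 in the table and 139 among the genes tested, and 221 tested genes were structural RNAs. Counts of copied, overlapping and read-through genes depend on how fragments shared between loci were assigned.

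Named genes followed a rule. ATF7IP, SETDB1, CYB5R2 and PARK7 were always named. For each comparison with Control, the rule took the 10 highest and 10 lowest log2 fold changes among called genes with at least 2-fold change, in both hairpins where they were compared, and a mean of at least 5 CPM. Where fewer were called, the list was filled from uncalled genes that met the other conditions. The rule took 5 and 5 genes for SETDB1 against ATF7IP knockdown, 5 and 5 for all 3 knockdown libraries, and up to 4 members of each described list with a mean of at least 1 CPM. The rule was also repeated without read-through loci and structural RNAs, a choice made after the values were seen. Genes named outside the rule are marked as such.

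The 36 gene lists covered chromatin, stress, lipid, liver and cell type genes. Lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the lists. The preset correlation is an assumption that treats members as nearly independent, and its false calls were not simulated. The 2 ATF7IP hairpins differed by medians of −0.50 in interferon-stimulated, −0.56 in ribosomal protein and −0.70 in histone genes. In heat shock genes they differed by 0.01. Members of some lists thus moved together between libraries, and the p-values of such lists may be too small. The estimated correlation and fry rest on the 1 residual degree of freedom, and their power to call a list was not measured. An absent call under either therefore does not decide whether a list changed. A list's median log2 fold change was also set beside the medians of 10000 random lists matched on mean expression. Members were also counted with p-values "adjusted over the list alone".

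Gene calls and correlations across genes were compared with simulated libraries drawn from the fitted model with no group differences, in 100 runs for correlations and 10 for calls. The pipeline was tested on simulated data in 5 runs with 200 changed genes per comparison among 16481 genes. The changed genes were drawn from genes with a mean of at least 1 CPM. It called 29.9% of 2-fold, 89.9% of 4-fold and 98.2% of 8-fold changes between ATF7IP knockdown and Control. Between SETDB1 knockdown and Control it called 17.0%, 83.3% and 98.2%. It also called a mean of 34.2 and 32.6 unchanged genes per run in these comparisons. So many planted changes make the Benjamini-Hochberg cutoff less strict than with the 13 and 12 genes called here. The shares may therefore be too high for these data, where SETDB1 in its own knockdown, at −1.99, was not called. Simulated libraries with no differences gave at least 7 calls for ATF7IP knockdown, 6 for SETDB1 knockdown and 5 for their difference. The adjusted p did not hold its nominal level there.

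The alternatives were DESeq2 size factors in place of TMM, library totals alone, no filter, a filter of at least 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-trend, the version 4 form of the edgeR fit, a non-robust fit, fits without the SETDB1 or the Control library, other thresholds, fold sizes and prior counts, and each ATF7IP hairpin alone as values. The comparisons, tests, gene lists, naming rule and these alternatives were fixed before the data were examined. Counts divided by 4, and the exclusion of read-through loci and structural RNAs, were added after seeing the data. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Levels of genes that mark sex were not reported, and some single-gene results are not reported here.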

Results

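Per the labels, the libraries measured polyA RNA from sorafenib-treated HepG2 cells that carried a Control hairpin, 1 of 2 ATF7IP hairpins or a SETDB1 hairpin. Control and SETDB1 knockdown had 1 library each and ATF7IP knockdown had 2, so Control and SETDB1 values have no replicates. Library totals were 70236882 counts in Control, 71225287 and 73791097 in the ATF7IP hairpins and 72599883 in SETDB1 knockdown, with an assumed 4 counts per fragment. The number of genes above 0 was 18291 in Control, 18256 and 18479 in ATF7IP hairpins 1 and 2, and 18572 in SETDB1 knockdown. Ribosomal RNA genes took 0.325% of counts in Control, 0.489% and 0.408% in the ATF7IP hairpins, and 0.721% in SETDB1 knockdown. Ribosomal protein genes took 4.604%, 5.79%, 4.10% and 4.43% in the same order. Sets of 4 CPM values give Control, ATF7IP hairpin 1, ATF7IP hairpin 2 and SETDB1 knockdown in that order, and positions are on the hg38 assembly (RefSeq). Adjusted p-values of single genes come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

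ATF7IP (chromosome 12, 14365682 to 14502930), a cofactor of the histone H3 lysine 9 methyltransferase SETDB1, was at 59.1 CPM in Control, 18.3 and 18.8 in its 2 knockdown libraries and 97.8 in SETDB1 knockdown. The log2 fold change of ATF7IP in its own knockdown was −1.67 ± 0.24 and missed the threshold (edgeR adjusted p = 0.0571). In SETDB1 knockdown it was 0.73 ± 0.29 (edgeR adjusted p = 1). SETDB1 (chromosome 1, 150926263 to 150964737) was at 47.7, 52.1, 46.8 and 11.99 CPM. Its log2 fold change was −1.99 ± 0.31 in SETDB1 knockdown (edgeR adjusted p = 0.117) and 0.05 ± 0.26 in ATF7IP knockdown (edgeR adjusted p = 0.987). Between the 2 knockdowns both genes passed the test, with log2 fold changes of 2.40 ± 0.24 for ATF7IP (edgeR adjusted p = 0.00692) and −2.04 ± 0.29 for SETDB1 (edgeR adjusted p = 0.038). Either target passed the threshold against Control under other tests, with ATF7IP at an adjusted p of 9.94e-06 and SETDB1 at 2.45e-05 under DESeq2. Over all alternatives the adjusted p ranged up to 0.208 for ATF7IP and 0.293 for SETDB1.

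The series title names CYB5R2, a cytochrome b5 reductase, and PARK7, which encodes the redox-sensing protein DJ-1. CYB5R2 (chromosome 11, 7665095 to 7674267, overlapping PPFIBP2) had 5 counts in Control, 36 and 86 in the ATF7IP hairpins and 43 in SETDB1 knockdown. At the assumed 4 counts per fragment this was 1 fragment in Control against 9, 22 and 11. The ratios to Control were 8.87 (95% interval 1.23 to 389), 19.9 (3.22 to 822) and 10.7 (1.56 to 463). CYB5R2 was not called in ATF7IP knockdown (edgeR adjusted p = 0.276) or SETDB1 knockdown (edgeR adjusted p = 0.916), and at this depth the size of the difference was not determined. PARK7 mRNA (chromosome 1, 7961711 to 7985505) was at 246, 333, 282 and 255 CPM. Its log2 fold change was 0.32 ± 0.27 in ATF7IP knockdown (edgeR adjusted p = 0.828) and 0.05 ± 0.31 in SETDB1 knockdown (edgeR adjusted p = 1).

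**Figure D1:**
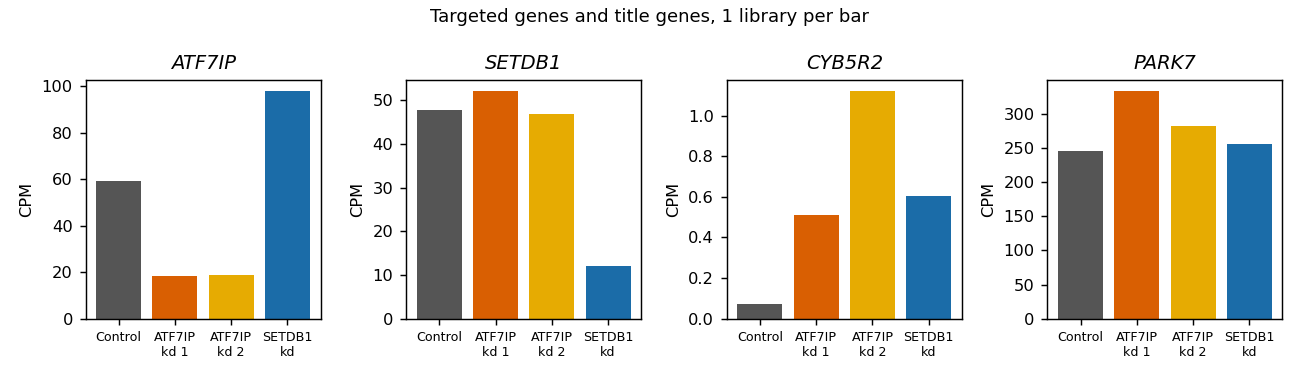
Level in CPM of ATF7IP, SETDB1, CYB5R2 and PARK7, with 1 bar per library. ATF7IP was at 18.3 and 18.8 CPM with its hairpins against 59.1 in Control, SETDB1 was at 11.99 CPM with its hairpin against 47.7, and CYB5R2 had 5 counts in Control.

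ATF7IP knockdown against Control asked which transcripts differed once ATF7IP was depleted under sorafenib. The named genes called lower in both hairpins were MAMDC2, TGFBR2, ANXA1, ELF3, TIMP3 and MMP24. MAMDC2 (chromosome 9, 70043581 to 70226972, overlapping its antisense RNA MAMDC2-AS1), an extracellular matrix protein, was at 51.0 CPM in Control and 6.28 and 5.15 in the hairpins, a log2 fold change of −3.16 ± 0.27 (edgeR adjusted p = 0.00801). TGFBR2 (chromosome 3, 30606356 to 30694142), a receptor for TGF-beta, fell from 58.1 to 12.7 and 12.9 CPM, with −2.18 ± 0.25 (edgeR adjusted p = 0.024). ANXA1 (chromosome 9, 73151865 to 73170393), a calcium-dependent membrane-binding protein, fell from 183 to 45.04 and 32.01 CPM, with −2.25 ± 0.27 (edgeR adjusted p = 0.0364). ELF3 (chromosome 1, 202010587 to 202017183), an epithelial transcription factor, fell from 68.0 to 18.1 and 15.7 CPM, with −2.01 ± 0.25 (edgeR adjusted p = 0.0426). TIMP3 (chromosome 22, 32801705 to 32863041, inside SYN3), an inhibitor of matrix metalloproteinases, fell from 169 to 44.4 and 27.8 CPM, with −2.22 ± 0.30 (edgeR adjusted p = 0.0497). The metalloproteinase gene MMP24 (chromosome 20, 35226690 to 35276998, overlapping MMP24OS and a read-through locus) fell from 40.5 to 10.3 and 7.09 CPM, with −2.22 ± 0.30 (edgeR adjusted p = 0.0497).

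The test called 13 genes, 3 higher and 10 lower, and with DESeq2 size factors in place of TMM it called 3, 1 higher and 2 lower. RN7SL2 (chromosome 14, 49862551 to 49862849), the RNA of the signal recognition particle, was at 0.892, 6.04, 6.41 and 28.3 CPM and was called higher with 2.80 ± 0.36 (edgeR adjusted p = 0.0492). The share of counts from RN7SL genes was 0.000225% in Control, 0.00118% and 0.00127% in the ATF7IP hairpins and 0.00448% in SETDB1 knockdown. Ribosomal RNA shares were likewise lowest in Control and highest in SETDB1 knockdown, so the RN7SL2 call is uncertain in these polyA libraries. The other calls were genes with a mean under 5 CPM and are named after their values were seen. DISC1 was called lower, with 125 counts in Control and 4 and 3 in the hairpins, and Control exceeded ATF7IP knockdown 32.8-fold (95% interval 8.36 to 283). DAPP1 was called lower, at 2.91, 0.170, 0.169 and 0.183 CPM, which is at or near the floor in all 3 knockdown libraries. NPIPA7, a member of a family of near-identical genes, was at 0 counts in Control and at least 11.7-fold higher in ATF7IP knockdown, while the sum of 6 NPIPA genes was at 31.5, 49.5, 35.4 and 34.2 CPM. The remaining 3 calls were the read-through loci NDUFC2-KCTD14, at least 97.9-fold lower, CCDC169-SOHLH2, at least 10.7-fold lower, and TNFSF12-TNFSF13, at least 30.0-fold higher. Fragments of such copied and read-through loci can be assigned to their neighbours, so their calls are uncertain.

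Among uncalled genes that met the rest of the naming rule, the cytokine gene IL6 was at 24.3, 66.1, 82.7 and 29.1 CPM (edgeR adjusted p = 0.124). The cytokine gene IL1A was at 12.9, 2.86, 2.37 and 3.11 CPM (edgeR adjusted p = 0.0571), and the hypoxia-responsive gene ANKRD37 was at 13.9, 4.49, 1.49 and 4.37 CPM. ALPP, the placental alkaline phosphatase gene, was at 452, 73.9, 21.0 and 197 CPM (edgeR adjusted p = 0.62), and its close copy ALPG was at 16.4, 1.16, 0 and 8.24 CPM. Summed, this pair was at 468, 75.1, 21.0 and 205 CPM. IGFN1 was at 4.39, 11.5, 25.5 and 2.71 CPM and the interferon-induced antiviral gene RSAD2, named by the repeated rule, at 17.2, 53.4, 37.9 and 30.4 CPM. The fill also named the uncalled read-through loci DNAAF4-CCPG1, UBE2F-SCLY and INO80B-WBP1, the ribosomal RNA genes RNA28SN3 and RNA28SN4, the signal recognition particle RNA RN7SL1 and TALAM1, an antisense RNA of MALAT1. Under the size rule 332 genes were at least 2-fold from Control in both hairpins, 126 higher and 206 lower, against a mean of 116.1 in simulated unchanged libraries (86 to 146).

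In simulated unchanged libraries the same test called a mean of 14.7 genes (7 to 23), so the 13 calls do not exceed what no difference would give, while 1511 genes had an unadjusted p under 0.05 against a simulated mean of 826.5 (775 to 911). Without the SETDB1 library the test called 34 genes, 6 higher and 28 lower.

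**Figure D2:**
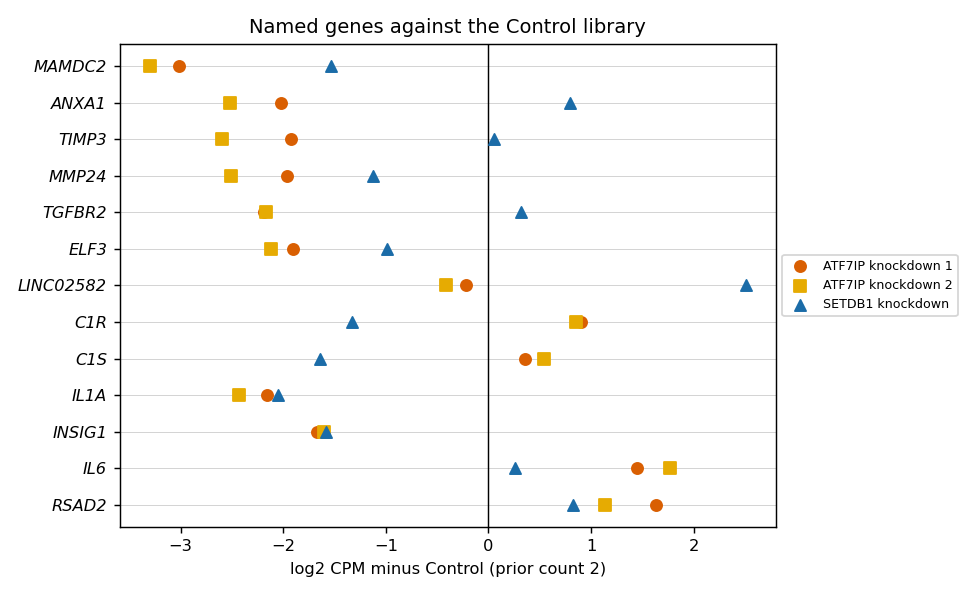
Log2 CPM minus Control (prior count 2) of 13 named genes, with 1 point per knockdown library. MAMDC2 was below Control in all 3 knockdown libraries, while ANXA1 was at 45.04 and 32.01 CPM with the ATF7IP hairpins and at 317 CPM in SETDB1 knockdown against 183 in Control.

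Gene lists with camera calls in ATF7IP knockdown numbered 7, with 1 higher and 6 lower. Each adjusted p of a list below is from camera with the preset correlation, and with an estimated correlation 0 of the 7 were called (adjusted p = 0.983 with an estimated correlation for each). With fry 0 were called either (smallest adjusted p = 0.097). These 2 alternatives rest on 1 residual degree of freedom and their power was not measured, so they do not decide whether the calls hold. Interferon-stimulated genes, which respond to antiviral signals, rose together, with 31 of 35 above 0 and a median log2 fold change of 0.50 (adjusted p = 5.03e-05). The median was 0.67 in hairpin 1 and 0.23 in hairpin 2, 9 members were at least 2-fold higher, and edgeR called 0, also when adjusted over the list alone. IFI6 was at 24.1, 100.2, 25.5 and 8.39 CPM, IFI27 at 3.15, 32.9, 4.47 and 1.01, and MX2 at 1.04, 9.72, 3.36 and 0.380.

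The targets of NRF2, the transcription factor of the antioxidant response, fell together, with 19 of 25 below 0 and a median of −0.30 (adjusted p = 0.0046), which was −0.15 in hairpin 1 and −0.42 in hairpin 2. Adjusted over the list alone, 4 NRF2 targets were called lower. AKR1C3, an aldo-keto reductase, was at 35.3, 13.6, 17.6 and 37.1 CPM, and TXNRD1, a thioredoxin reductase, at 1422, 693, 686 and 1239.6 CPM. Genes of cholesterol synthesis and uptake fell together, with 19 of 25 below 0, a median of −0.29 (adjusted p = 0.0046) and 5 called lower when adjusted over the list alone. The cholesterol median was −0.39 in hairpin 1 and −0.22 in hairpin 2. STARD4, a cholesterol carrier, was at 49.3, 17.1, 27.2 and 36.0. The p53 targets fell together, with 18 of 21 below 0 and a median of −0.38 (adjusted p = 0.0046), which was −0.53 in hairpin 1 and −0.05 in hairpin 2. MDM2, the ubiquitin ligase of p53, was at 334, 163, 254 and 224 CPM.

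Stellate and fibroblast markers fell together, with 9 of 11 below 0, a median of −0.40 (adjusted p = 0.0046) and 4 called lower when adjusted over the list alone. The median was −0.54 in hairpin 1 and −0.41 in hairpin 2. The proteoglycan genes LUM and DCN were at 81.6, 26.0, 25.9 and 92.5 CPM and at 12.8, 4.68, 5.30 and 12.2 CPM. Epithelial junction genes fell together, with 11 of 13 below 0, a median of −0.45 (adjusted p = 0.00821) and 1 called lower when adjusted over the list alone. The junction gene median was −0.36 in hairpin 1 and −0.47 in hairpin 2. The called gene was DSP, which encodes the desmosome protein desmoplakin, at 434, 144, 112 and 403 CPM. Mesenchymal genes fell together as well, with 19 of 23 below 0 and a median of −0.32 (adjusted p = 0.00821), which was −0.22 in hairpin 1 and −0.45 in hairpin 2. FN1, which encodes fibronectin, was at 297, 172, 134 and 151 CPM, while the gelatinase gene MMP2 was at 6.85, 14.8, 14.1 and 8.34 CPM.

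**Figure D3:**
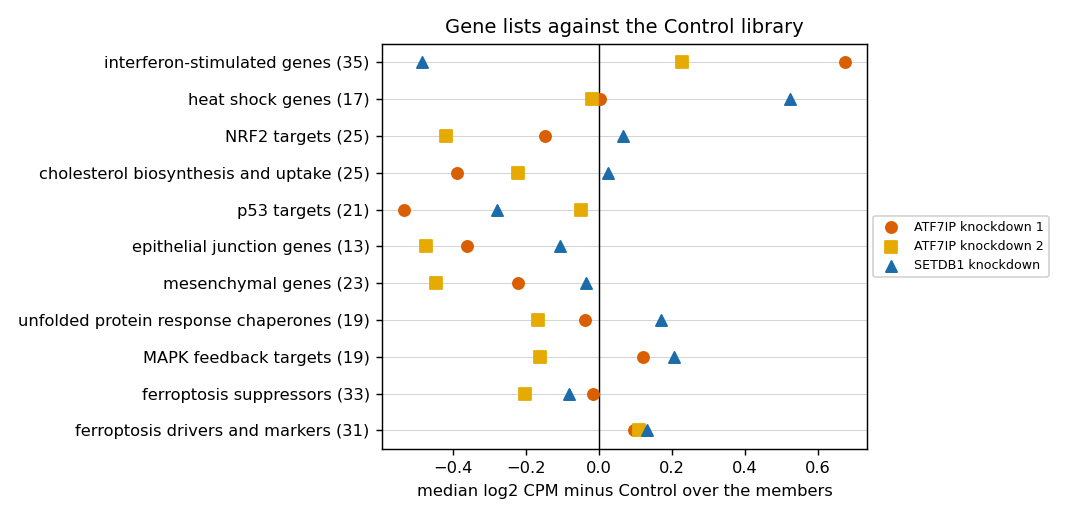
Median log2 CPM minus Control over the tested members of 11 gene lists, with 1 point per knockdown library. Interferon-stimulated genes were above Control in both ATF7IP hairpins (medians of 0.67 and 0.23) and below it in SETDB1 knockdown (−0.48), and heat shock genes were above it in SETDB1 knockdown (0.52).

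SETDB1 knockdown against Control asked which transcripts differed once SETDB1 itself was depleted under sorafenib, with 1 library on each side. CALB1, which encodes the calcium-binding protein calbindin, rose from 0.403 to 9.76 CPM, a log2 fold change of 4.59 ± 0.59 (edgeR adjusted p = 0.0406). ZNF114, a zinc finger gene, was called higher with 2 counts in Control and 212 in SETDB1 knockdown (edgeR adjusted p = 0.0336). PSG9, a pregnancy-specific glycoprotein gene with close copies, was at 0 counts in Control and at least 18.5-fold higher in SETDB1 knockdown (edgeR adjusted p = 0.0175). The sum of 10 genes of this family was at 36.0, 24.9, 16.4 and 67.4 CPM, so the PSG9 call is uncertain. CALB1, ZNF114 and PSG9 had means under 5 CPM and were chosen after their values were seen. U2AF1 (chromosome 21, 43092956 to 43107578), a splicing factor, was at 33.4, 35.8, 35.6 and 2.87 CPM and was called lower with −3.54 ± 0.34 (edgeR adjusted p = 0.0104). Summed with its copy U2AF1L5 it was at 89.5, 132, 122 and 113 CPM, so the U2AF1 call is uncertain.

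The test called 12 genes, 8 higher and 4 lower, and with DESeq2 size factors it called 7, 5 higher and 2 lower. RN7SL2 was called higher with 4.98 ± 0.42 (edgeR adjusted p = 0.0104), and so was RN7SL1 (chromosome 14, 49586580 to 49586878), at 1.02, 5.61, 5.41 and 17.1 CPM with 4.06 ± 0.43 (edgeR adjusted p = 0.015). Ribosomal RNA genes also took a larger share of SETDB1 knockdown than of Control (0.721% against 0.325%), so both RN7SL calls are uncertain. The read-through locus SENP3-EIF4A1 (chromosome 17, 7561992 to 7579006) was called higher at 3.12, 6.92, 5.54 and 40.3 CPM with 3.69 ± 0.39 (edgeR adjusted p = 0.015). The other calls were NPIPA7, at least 10.1-fold higher, and the read-through loci TNFSF12-TNFSF13, at least 32.2-fold higher, SUGT1P4-STRA6LP-CCDC180, at least 19.8-fold lower, TMX2-CTNND1, at least 17.3-fold lower, and RPL36A-HNRNPH2, at least 15.2-fold lower. These 5 were also chosen after their values were seen, and their calls are uncertain.

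Of the uncalled genes that met the rest of the naming rule, the long noncoding RNA LINC02582 (chromosome 18, 73324941 to 73349889) was at 4.88, 4.20, 3.65 and 27.9 CPM (edgeR adjusted p = 0.0899). The ribosomal RNA precursor gene RNA45SN5 was at 125, 239, 147 and 657 CPM. TCIM was at 57.2, 42.2, 21.99 and 13.1 CPM, SLC12A3, a salt transporter, at 20.8, 23.3, 4.35 and 3.43, and NOMO3 at 255, 151, 349 and 41.0 CPM. Summed, the 3 NOMO copies were at 628, 648, 701 and 742 CPM. In the repeated rule, the cytokine genes IL11 and CXCL8 were at 3.03, 10.2, 5.74 and 11.5 CPM and at 7.28, 11.6, 28.4 and 26.3 CPM. ID3, an inhibitor of DNA-binding transcription factors, was at 233, 274, 147 and 64.2 CPM, and COL15A1, a collagen gene, at 33.5, 13.1, 9.48 and 9.43 CPM. Under the size rule 416 genes were at least 2-fold from Control, 175 higher and 241 lower, against a mean of 443 in simulated unchanged libraries (394 to 496).

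In simulated unchanged libraries the test called a mean of 17.4 genes (6 to 26), and 796 genes had an unadjusted p under 0.05 against a simulated mean of 826.5, so the number of calls does not exceed what no difference would give. With no filter on low counts edgeR called 0 genes, while DESeq2 called 49 and limma-trend 6 in the filtered table.

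Gene lists with camera calls in SETDB1 knockdown numbered 6, with 3 higher and 3 lower, and with an estimated correlation or fry 0 of them were called. Heat shock genes, which encode protein-folding chaperones, rose together, with 15 of 17 above 0 and a median of 0.52 (adjusted p = 3.33e-05, and adjusted p = 0.934 with an estimated correlation). HSPA1A was at 1328, 922, 1412 and 3098 CPM, and HSP90AA1 at 2083, 2196, 3085 and 4675 CPM. This was also the library with the highest shares of ribosomal RNA (0.721%) and RN7SL RNA (0.00448%). Zinc finger genes with a ZNF symbol, many of which encode KRAB repressors, rose together, with 243 of 371 above 0, a median of 0.14 (adjusted p = 0.00643, and adjusted p = 0.934 with an estimated correlation) and 1 called, ZNF114. The zinc finger median was also 0.14 above Control in ATF7IP hairpin 2, and −0.07 in hairpin 1. These 2 hairpins differed by a median of 0.21, so the rise was not particular to SETDB1 knockdown. Feedback targets of MAPK signalling rose together, with 15 of 19 above 0 and a median of 0.21 (adjusted p = 0.0212, and adjusted p = 0.934 with an estimated correlation). SPRY4, an inhibitor of receptor tyrosine kinase signalling, was at 13.7, 14.1, 14.1 and 25.1 CPM. The MAPK median was 0.12 in ATF7IP hairpin 1 and −0.16 in hairpin 2.

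Interferon-stimulated genes fell together in SETDB1 knockdown, with 27 of 35 below 0, a median of −0.48 (adjusted p = 0.0119, and adjusted p = 0.934 with an estimated correlation) and 10 at least 2-fold lower. IRF9, a transcription factor of the interferon response, was at 19.3, 29.6, 18.02 and 6.37 CPM. The p53 targets fell together, with 17 of 21 below 0 and a median of −0.28 (adjusted p = 0.00643, and adjusted p = 0.934 with an estimated correlation). Acute-phase protein genes had 8 members tested and a median of −0.96 (adjusted p = 0.0434, and adjusted p = 0.934 with an estimated correlation). Without TMM they were not called (adjusted p = 0.0506). The acute-phase median was also below Control in ATF7IP hairpin 1 (−0.58) and hairpin 2 (−0.50), so a fall was not particular to SETDB1 knockdown. Against these hairpins SETDB1 knockdown had medians of −0.62 and −0.57. Only C3 and CFB had a mean of at least 1 CPM. From Control to SETDB1 knockdown CFB went from 664 to 435 counts, SAA1 from 111 to 42, SAA2 from 58 to 8 and ITIH4 from 20 to 3. HPX went the other way from 20 to 35, SERPINA3 from 7 to 16 and FGG from 19 to 20. Adjusted over the list alone, 1 acute-phase gene was called lower, and in the other called lists of this comparison that count was 0 apart from ZNF114. C3, the central complement component, was at 135, 159, 230 and 56.0 CPM.

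SETDB1 against ATF7IP knockdown tested the difference between the effects of the 2 targets, and the Control library cancelled out of it. ANXA1 was higher in SETDB1 knockdown, with a log2 fold change of 3.04 ± 0.28 (edgeR adjusted p = 0.00636). TGFBR2, at 72.1 CPM in SETDB1 knockdown, was higher with 2.49 ± 0.25 (edgeR adjusted p = 0.00692), and TIMP3, at 175 CPM there, with 2.28 ± 0.30 (edgeR adjusted p = 0.0299). LINC02582 was higher with 2.83 ± 0.30 (edgeR adjusted p = 0.00969). The neighbouring genes C1R (chromosome 12, 7080219 to 7092445) and C1S (chromosome 12, 7060718 to 7071032), which encode proteases of the first complement component, were lower in SETDB1 knockdown. C1R was at 38.6, 71.9, 69.9 and 15.3 CPM with −2.21 ± 0.28 (edgeR adjusted p = 0.0247). C1S was at 22.8, 29.2, 33.2 and 7.28 CPM with −2.10 ± 0.30 (edgeR adjusted p = 0.0387).

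The test called 28 genes, 18 higher and 10 lower in SETDB1 knockdown, and with DESeq2 size factors it called 11, 8 higher and 3 lower. Among them were ATF7IP and SETDB1 themselves, U2AF1 with −3.64 ± 0.32 (edgeR adjusted p = 0.00636), SENP3-EIF4A1 with 2.69 ± 0.29 (edgeR adjusted p = 0.01) and RN7SL2 with 2.18 ± 0.29 (edgeR adjusted p = 0.0307). Called genes chosen after their values were seen were CALB1 with 5.90 ± 0.48 (edgeR adjusted p = 0.00482) and the proteoglycan LUM with 1.83 ± 0.23 (edgeR adjusted p = 0.0247). Of the 28 calls, 9 were read-through loci or structural RNAs. The same test called a mean of 16.5 genes in simulated unchanged libraries (5 to 27), and 17 of the calls had a mean of at least 5 CPM against a simulated mean of 9.7 (1 to 17). An unadjusted p under 0.05 was found for 1669 genes against a simulated mean of 826.

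Gene lists with camera calls in this comparison numbered 5, and with an estimated correlation or fry 0 of them were called. Interferon-stimulated genes were lower in SETDB1 than in ATF7IP knockdown, with 34 of 35 below 0, a median of −0.76 (adjusted p = 1.77e-10, and adjusted p = 0.912 with an estimated correlation) and 11 called when adjusted over the list alone. The medians were −1.04 against hairpin 1 and −0.46 against hairpin 2. The preset correlation treats the members as nearly independent, while the 2 hairpins themselves differed by a median of −0.50 in this list. Heat shock genes were higher, with 16 of 17 above 0, a median of 0.70 (adjusted p = 5.38e-06, and adjusted p = 0.912 with an estimated correlation) and 6 called when adjusted over the list alone. NRF2 targets were higher, with 20 of 25 above 0, a median of 0.33 (adjusted p = 0.000963, and adjusted p = 0.912 with an estimated correlation) and 3 called when adjusted over the list alone. The heat shock medians were 0.71 against hairpin 1 and 0.60 against hairpin 2, and those of NRF2 targets 0.34 and 0.43. Chaperones of the unfolded protein response were higher, with 17 of 19 above 0 and a median of 0.29 (adjusted p = 0.0103, and adjusted p = 0.912 with an estimated correlation), and the median was 0.11 against hairpin 1 and 0.35 against hairpin 2. HSPA5, the main chaperone of the endoplasmic reticulum, was at 1702, 1260.4, 1074 and 1971 CPM. Epithelial junction genes were higher with a median of 0.42 (adjusted p = 0.0355, and adjusted p = 0.912 with an estimated correlation), which was 0.38 against hairpin 1 and 0.37 against hairpin 2.

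In all 3 knockdown libraries, 98 genes were at least 2-fold from Control in the same direction, 52 higher and 46 lower. INSIG1 (chromosome 7, 155297878 to 155310235), a brake on cholesterol synthesis, was at 63.4, 19.9, 20.9 and 21.1 CPM, with an edgeR adjusted p of 0.0608 in ATF7IP knockdown and 0.296 in SETDB1 knockdown. With INSIG1, the naming rule took MAMDC2, IL1A, ANKRD37 and the read-through locus SERF2-C15ORF63 from the 22 genes that were lower with a mean of at least 5 CPM, and MAMDC2 was at 17.6 CPM in SETDB1 knockdown. From the 9 such genes that were higher, it took the read-through or structural loci DNAAF4-CCPG1, RN7SL2, RNA28SN4, RN7SL1 and UBE2F-SCLY. Simulated unchanged libraries gave a mean of 54.05 such genes (33 to 76), and taking each other library in turn as the reference gave 82, 84 and 119. Genes called in both comparisons in the same direction were RN7SL2, NPIPA7 and TNFSF12-TNFSF13, a count of 3 against a mean of 6.4 in simulated unchanged libraries.

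Across the 16900 genes, which are not independent replicates, the ATF7IP and SETDB1 fold changes correlated with a Pearson r of 0.508 against a mean of 0.578 in simulated unchanged libraries with the same shared Control. Their covariance was 0.293 against a simulated mean of 0.208 over all genes, and 0.0720 against 0.0902 over the 11054 genes with a mean of at least 5 CPM. The fold changes of the 2 ATF7IP hairpins correlated at 0.597 against a simulated 0.503. For genes with a mean of at least 5 CPM these values were 0.594 and 0.501. The lone Control library enters every one of these fold changes, so a deviation of that library alone would appear as a shared change. For the 2 ATF7IP hairpins, pairings that share no library argue against this as the whole cause. Hairpin 1 minus Control correlated with hairpin 2 minus SETDB1 at 0.198, against a highest simulated value of 0.0366. The other such pairing of the hairpins gave 0.148 against 0.0457. Changes shared by ATF7IP and SETDB1 knockdown are not covered by these pairings.

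With the filterByExpr filter, camera called none of the following lists in either comparison with Control. Ferroptosis suppressors, such as the lipid peroxidase GPX4, had 33 members tested with medians of −0.12 in ATF7IP knockdown (adjusted p = 0.294) and −0.08 in SETDB1 knockdown (adjusted p = 0.839). The suppressor median was −0.02 in hairpin 1 and −0.20 in hairpin 2. Ferroptosis drivers had 31 members with medians of 0.11 (adjusted p = 0.554) and 0.13 (adjusted p = 0.424). Cytochrome b5 and its reductases had 11 members with medians of 0.14 (adjusted p = 0.465) and −0.14 (adjusted p = 0.813), and for SETDB1 knockdown the mean was 0.25. Iron handling genes had medians of −0.09 (adjusted p = 0.689) and 0.00 (adjusted p = 0.937), and the hairpins lay on opposite sides of 0 with −0.12 and 0.03. The 25 genes of H3 lysine 9 methylation and the HUSH silencing complex had medians of 0.08 (adjusted p = 0.734) and 0.02 (adjusted p = 0.813), with means below 0 in both comparisons. This list includes the hairpin targets ATF7IP and SETDB1, which enter those means. Clustered protocadherins, of which 32 were tested, had medians of 0.61 (adjusted p = 0.0924) and 0.69 (adjusted p = 0.0933), and 2 were called higher in ATF7IP knockdown when adjusted over the list alone. The ATF7IP value rested on hairpin 2, with a median of 0.97 against −0.02 in hairpin 1. With a filter at 1 CPM camera called the protocadherins in ATF7IP knockdown (adjusted p = 0.000605) and between the knockdowns (adjusted p = 0.0392). With all tested members the adjusted p in ATF7IP knockdown was 0.983 with an estimated correlation. Between the knockdowns camera did not call the protocadherins with all tested members. There SETDB1 knockdown had a median of 0.30 against hairpin 1 and −0.42 against hairpin 2. Germline and cancer-testis genes had medians of 0.10 (adjusted p = 0.689) and 0.21 (adjusted p = 0.424).

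The cell type genes were measured on the library total. Of 30 hepatocyte identity genes, 19 were at or under the floor in every library, and 11 of these were at 0 in all 4, among them ALB, APOB, AFP and TTR, which encode secreted liver proteins. Only 4 of the 30 had a mean of at least 1 CPM, namely CPS1 at 437 CPM, FOXA1 at 12.6, CEBPA at 10.3 and NR5A2 at 1.81. Of 18 acute-phase genes, 10 were at or under the floor in every library and 2 had a mean of at least 1 CPM, C3 at 146 and CFB at 8.62. Of 18 epithelial junction genes 10 had a mean of at least 1 CPM, with the keratin genes KRT18 at 684 and KRT8 at 350. At or under the floor in every library were 6, namely CDH1, EPCAM, GRHL2, KRT19, CLDN2 and CLDN6. All 23 mesenchymal genes had a mean of at least 1 CPM, with VIM, the vimentin gene, at 472. Of 14 cholangiocyte and stem cell markers 7 had a mean of at least 1 CPM, with KRT7 at 1429.6. Of 14 stellate and fibroblast markers 8 did, with COL3A1 at 208. Blood markers reached 1 CPM in 2 of 17 genes, endothelial markers in 2 of 14 and neuronal genes in 4 of 21.

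**Figure D4:**
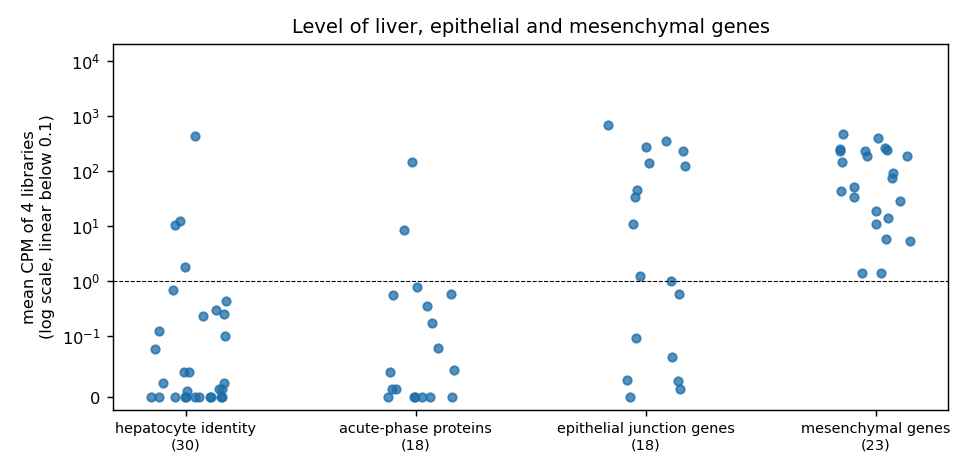
Mean CPM over the 4 libraries of each gene in 4 lists, on a log axis that is linear below 0.1, with a dashed line at 1 CPM. Of 30 hepatocyte genes 4 lay at or above the line, against 2 of 18 acute-phase genes, 10 of 18 epithelial junction genes and 23 of 23 mesenchymal genes.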

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

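All tests that weigh explanations here were chosen after the results were seen. The results below stood out because the test of SETDB1 against ATF7IP knockdown, which is the difference between the effects of the 2 knockdowns on the same Control, passed its threshold for them.

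Interferon-stimulated genes lay apart in the 2 knockdowns, with a median log2 difference of −0.76 for SETDB1 minus ATF7IP knockdown (camera adjusted p = 1.77e-10, and adjusted p = 0.912 with an estimated correlation). This difference does not use the Control library, and 95% of matched random lists had medians of −0.15 to 0.15. Spread between single libraries stays open, because the 2 ATF7IP hairpins themselves differed in this list by a median of −0.50, outside the −0.16 to 0.14 of matched random lists, and SETDB1 knockdown has no second library. A response to the SETDB1 hairpin construct rather than to loss of SETDB1 stays open as well, and it cannot be told apart from a target effect with 1 SETDB1 hairpin in the series. An effect of the target genes on interferon signalling is therefore a hypothesis that may be followed up with further hairpins. The heat shock, NRF2, epithelial junction and chaperone lists below rest on the same single SETDB1 library and hairpin. Library spread and a response to the construct therefore stay open for them too.

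Heat shock genes were higher in SETDB1 than in ATF7IP knockdown with a median log2 difference of 0.70 (adjusted p = 5.38e-06). NRF2 targets were higher with a median of 0.33 (adjusted p = 0.000963). Epithelial junction genes were higher with a median of 0.42 (adjusted p = 0.0355), and chaperones of the unfolded protein response with a median of 0.29 (adjusted p = 0.0103). With an estimated correlation, which rests on 1 residual degree of freedom and whose power was not measured, each of these 4 lists had an adjusted p of 0.912.

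Single genes were flagged from 28 calls. The same test called a mean of 16.5 genes (5 to 27) in simulated unchanged libraries, so many of the 28 may be false. The 2 targets stood apart, as the hairpins were designed to make them. Their log2 fold changes of SETDB1 over ATF7IP knockdown were 2.40 for ATF7IP (edgeR adjusted p = 0.00692) and −2.04 for SETDB1 (edgeR adjusted p = 0.038). ANXA1 was higher in SETDB1 knockdown with 3.04 (edgeR adjusted p = 0.00636), TGFBR2 with 2.49 (edgeR adjusted p = 0.00692) and TIMP3 with 2.28 (edgeR adjusted p = 0.0299). LINC02582 was higher with 2.83 (edgeR adjusted p = 0.00969). The complement genes C1R and C1S were lower with −2.21 (edgeR adjusted p = 0.0247) and −2.10 (edgeR adjusted p = 0.0387). The copied gene U2AF1 was lower with −3.64 (edgeR adjusted p = 0.00636), whereas its sum with U2AF1L5 differed by −0.16. The read-through locus SENP3-EIF4A1 was higher with 2.69 (edgeR adjusted p = 0.01), and RN7SL2 was higher with 2.18 (edgeR adjusted p = 0.0307). The calls of SENP3-EIF4A1 and RN7SL2 are uncertain.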

How the results depend on the processing

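The counts divided by 4 and the exclusion of read-through loci and structural RNAs were chosen after seeing the data, and the other alternatives were chosen beforehand. No value of a named gene, target or list called in the comparisons changed direction under any alternative run, but the number of calls depended on the test, the filter and the scaling. Where no cause is given, the cause was not tested. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers and nothing in the labels pairs them. With 1 library of Control and 1 of SETDB1 knockdown, leaving either out gives only the comparison between the remaining groups, and leaving out an ATF7IP hairpin leaves no residual for a test.

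Against 13, 12 and 28 genes called for ATF7IP knockdown against Control, SETDB1 knockdown against Control and SETDB1 against ATF7IP knockdown, DESeq2 size factors gave 3, 7 and 11. No filter on low counts gave 1, 0 and 8, with more genes tested, and the 0 of edgeR stood beside 49 by DESeq2, 6 by limma-trend and 796 genes at an unadjusted p under 0.05 in the reported fit. DESeq2 called 160, 49 and 173 genes, among them all 13, 12 and 28 of the reported calls. Limma-trend called 5, 6 and 9. Library totals without TMM gave 25 for ATF7IP knockdown, the non-robust fit 8 and the fit without the SETDB1 library 34. The filter at 1 CPM gave 53 for ATF7IP knockdown and 74 for the difference, the version 4 fit 42 and 66, and counts divided by 4 gave 83 and 89. Without read-through loci and structural RNAs, which removes such calls by construction, ATF7IP knockdown had 29 calls and SETDB1 knockdown 5. An adjusted p under 0.01 left 2, 0 and 9.

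ATF7IP in its own knockdown passed the threshold without TMM (−1.64, adjusted p = 0.0424), with the filter at 1 CPM (−1.67, adjusted p = 0.014), with DESeq2 (−1.67, adjusted p = 9.94e-06), with the version 4 fit (−1.67, adjusted p = 0.0163), without the SETDB1 library (−1.67, adjusted p = 0.0241), with counts divided by 4 (−1.68, adjusted p = 0.00689) and without read-through loci (−1.68, adjusted p = 0.0454). Its adjusted p over all alternatives ranged from 9.94e-06 to 0.208. SETDB1 in its own knockdown passed with the filter at 1 CPM (−1.99, adjusted p = 0.0339), DESeq2 (−1.99, adjusted p = 2.45e-05), the version 4 fit (−1.99, adjusted p = 0.0457) and counts divided by 4 (−1.99, adjusted p = 0.022), within a range of 2.45e-05 to 0.293. CYB5R2 had an adjusted p of 0.18 to 0.427 in ATF7IP knockdown and gave no value under the filter at 1 CPM, which removes it.

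Genes at least 2-fold from Control in both hairpins, SETDB1 knockdown and all 3 libraries numbered 149, 169 and 31 at a mean of at least 5 CPM, and 1169, 1517 and 375 at 1.5-fold. With either hairpin alone the count for ATF7IP knockdown was 644 to 763 and that for all knockdowns 125 to 166, since fewer libraries had to pass. The correlation of ATF7IP and SETDB1 fold changes was 0.431 at 5 CPM, 0.403 as Spearman's rho and 0.426 to 0.483 with either hairpin alone. Of 18 list calls by camera, 0 remained with an estimated correlation and 0 with fry. Both rest on 1 residual degree of freedom, and their power was not measured. The false calls of camera with the preset correlation were not measured either, so the list calls stay undecided. Of 69 named gene values, DESeq2 size factors ended 10 calls, no filter 17, limma-trend 13 and the non-robust fit 7, while DESeq2 added 24.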

Other observations

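All tests that weigh explanations in this part were chosen after the results were seen, as were the gene families summed.

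The 10 pregnancy-specific glycoprotein genes, which are near-identical placental genes, summed to 36.0 CPM in Control, 24.9 and 16.4 in ATF7IP hairpins 1 and 2 and 67.4 in SETDB1 knockdown, a log2 difference of 1.73 for SETDB1 over ATF7IP knockdown. The placental alkaline phosphatase genes ALPP and ALPG summed to a log2 difference from Control of −2.64 in ATF7IP hairpin 1, −4.48 in hairpin 2 and −1.19 in SETDB1 knockdown, and neither gene was called in ATF7IP knockdown (edgeR adjusted p = 0.62 for ALPP and 0.85 for ALPG). Ribosomal protein genes, with 82 members tested, were a median of 0.33 above Control in hairpin 1 and −0.23 in hairpin 2, and the 2 hairpins differed by −0.56. Correlations of fold changes that share no library were 0.198 for hairpin 1 minus Control with hairpin 2 minus SETDB1, against a highest value of 0.0366 in simulated unchanged libraries. The other such pairing of the ATF7IP hairpins gave 0.148 against a highest simulated value of 0.0457. The pairing of hairpin 1 minus hairpin 2 with Control minus SETDB1 gave 0.0525 against a highest simulated value of 0.0467. Over genes with a mean of at least 5 CPM the 3 pairings gave 0.315, 0.248 and 0.0732, against highest simulated values of 0.105, 0.107 and 0.0947.

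With the filterByExpr filter, camera called none of the following lists in any comparison, and their medians are given for ATF7IP and then SETDB1 knockdown against Control. Hypoxia and glycolysis genes had medians of 0.06 and 0.16, targets of the stress factor ATF4 −0.14 and 0.01, and inflammatory NF-kB genes −0.06 and −0.23. Proliferation genes had medians of 0.03 and −0.12, and replication-dependent histone genes 0.03 and 0.19. Fatty acid synthesis genes had −0.05 and 0.03, fatty acid oxidation genes −0.03 and 0.04, and the 4 metallothioneins tested −0.27 and 0.19. Hepatocyte identity genes, with 11 tested, had −0.28 and 0.07, and cytochrome P450 and bile acid genes 0.28 and 0.21. Imprinted genes had −0.19 and −0.07. Among other cell types, medians were −0.49 and 0.61 for 6 blood markers, −0.38 and 0.36 for 8 endothelial markers, −0.19 and −0.24 for 10 cholangiocyte markers and 0.00 and 0.42 for 9 neuronal genes. The ATF7IP hairpins lay on opposite sides of 0 for NF-kB, fatty acid synthesis, proliferation, hypoxia, metallothionein, histone and neuronal genes. With the filter at 1 CPM, camera called ATF4 targets between the knockdowns (adjusted p = 0.0392). With the filterByExpr filter, camera with an estimated correlation called 0 lists in any comparison, and so did fry, although the power of both was not measured. The median and the mean differed in sign for fatty acid oxidation, hypoxia and cholangiocyte genes in ATF7IP knockdown and for hepatocyte, imprinted and cholangiocyte genes in SETDB1 knockdown. Without TMM the median of fatty acid oxidation genes in ATF7IP knockdown and those of ATF4 and iron handling genes in SETDB1 knockdown changed sign.

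Liver genes that HepG2 cells are known for, such as ALB, APOB, AFP and TTR, were at 0 in all 4 libraries. Genes lost in the counting are argued against as the whole cause, since 0.862% of 116 ribosomal protein and proliferation genes were at or under the floor in every library against 63.3% of the hepatocyte list. Cells other than HepG2 stay open as a candidate explanation, since the 4 of 30 hepatocyte genes at a mean of at least 1 CPM restate the pattern and the series has no other line to compare. Loss of liver genes under sorafenib stays open too and cannot be told apart from this, because the series has 0 libraries without sorafenib.

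Calls on read-through loci may come from fragments divided between overlapping genes. Over 16 calls at 9 loci the median size of the log2 fold change was 6.55 for the read-through locus alone and 0.160 for the counts summed with its parts. The median does not decide, because the locus held at most a median of 6.85% of the summed counts, so that most sums would stay near 0 either way. SUGT1P4-STRA6LP-CCDC180 held up to 92.5% of them. Its sum with CCDC180 differed by −1.11 between SETDB1 knockdown and Control and by −0.81 between SETDB1 and ATF7IP knockdown. Its other parts are not in the sum, so this locus stays open as well. No biological explanation was tested for these loci.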
